A study of Mus musculus with 12 samples.

How the data were processed

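Bulk RNA sequencing covered trigeminal ganglia from female C57BL/6J mice aged 8 weeks, in 12 libraries and 4 groups of 3. The groups were untreated controls, mice 2 weeks after a 1.5 mm keratectomy of a random eye, mice with keratectomy and electrical stimulation, and uninjured mice with stimulation. Stimulation was given at 300 µA and 20 Hz for 4 min daily over 14 days. Stimulated mice were under isoflurane at each session, and injured mice received ketamine, xylazine and an analgesic, so these exposures move with the groups. Sham electrodes are mentioned in the submitters' description, but no library carries that label. The labels treat replicates as separate samples and do not say how many mice or which ganglion side went into each, so the p-values measure the spread between these libraries. Per the submitters' description the libraries were poly(A) enriched and sequenced as paired 150 bp reads. The title names diabetic neuropathy and KCNN channels, and no label mentions diabetes.

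The values analysed were the gene counts deposited by the authors, which are whole numbers for 56941 gene identifiers in each library. Per the file headers they came from featureCounts 2.0.6 with paired input and reads allowed in several overlapping genes, unstranded, on Ensembl 110 gene models for GRCm39. The headers do not ask for fragments to be counted, so single reads were counted. The submitters' processing notes list FastQC, Salmon 1.10.2 and DESeq2 instead. The plan fixed before the data were examined had taken the counts for Salmon estimates, and the same test was applied to the whole counts. The headers name a folder for HISAT output. The aligner version and the genome build of the alignments are not given in the sources used here. Counted reads, in units of 1e6, were 8.93, 8.40 and 8.50 in controls, 9.99, 10.8 and 8.40 after injury, 8.84, 8.40 and 8.66 after injury with stimulation, and 7.95, 8.59 and 10.4 with stimulation alone.

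The counting intervals and the RNA counted in them did not match. Of 21787 protein-coding intervals, 9006 (41.3%) had no GRCm38 exon at the same coordinates, and their median was 0.0584 CPM. Another 10512 (48.2%) lay only over GRCm38 exons of other genes and had a median of 3.03 CPM. The 746 intervals (3.42%) more than 50% covered by their own gene's GRCm38 exons had a median of 33.1 CPM. Intervals over GRCm38 exons were 36.0% of nuclear intervals and held 98.6% to 99.3% of nuclear counts per library. After all GRCm38 exons were moved by 1000000 bp they held 51.9% to 57.2%. The 73 ribosomal protein genes whose intervals were off their own GRCm38 exons had a median of 0.208 CPM, against 785 CPM for the 2 on them. These values are those of reads placed on GRCm38 coordinates and counted in GRCm39 intervals.

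Genes were therefore named by position, with GENCODE M21 models on GRCm38 and no conversion of coordinates. An interval took the name of a gene when it lay over the exons of exactly 1 GRCm38 gene and over at least 100 bp of them. Where several intervals qualified for a gene, the interval over the most exon bases took the name. This rule was chosen after the data were seen and named 9969 genes, of which 4771 were tested. Each named gene is measured only through the part of its exons under an interval. Because counting was unstranded and allowed several genes per read, reads from the opposite strand are included. Tests used all 13053 intervals that passed the filter, whether named or not.

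Differential expression used edgeR 4.0.16 quasi-likelihood tests (robust) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment in 1 fit of all 12 libraries. Genes or intervals were called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors, and errors of levels in CPM (counts scaled to 1e6 per library after TMM) are standard deviations of n = 3 libraries. The biological coefficient of variation was 0.235. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. For 42 lists with 900 entries, 888 entries matched a symbol of the deposited identifiers. The list tests used names by position, which left fewer members, such as 5 of 15 satellite glial markers. Counts of list members below refer to those tested, and 40 lists had at least 2 of them. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

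The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are Kcnn1 to Kcnn4. To these were added the 12 highest and 12 lowest fold changes per comparison among called genes with at least 1 CPM and no overlap between groups, without predicted genes and pseudogenes. Up to 4 members with the smallest p of each described list were also named. Some genes that the rule picks are not reported here. Lists of SK channels, injury response, nociceptors, glia, immune cells and other tissues were described whatever their p. Alternatives were DESeq2 size factors, no filter, at least 1 CPM, the DESeq2 test, voom with quality weights, only the groups compared, a replicate block, and leaving out each library in turn. Added after the data were seen were names as deposited, names from 90% of exon bases (10521 genes), removal of mitochondrial and rRNA-like intervals, and removal of a spline trend (4 degrees of freedom) on GC content and transcript length per library. The simulated comparison for the similarity of injury and stimulation alone was added then as well.

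The scripts were tested on simulated data made from all 12 libraries, with known changes placed in the injured ones and tested against control. Of 100 intervals raised or lowered 2-fold 55% were recovered, of 100 changed 4-fold 88%, and 7 unchanged intervals were called. A list raised 1.5-fold had an adjusted p of 2.6e-11, and 0 other lists were called. Correlations between comparisons that share libraries were set beside 20 simulations of unchanged groups.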

Results

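Of the 4 KCNN channel genes, which encode calcium-activated potassium channels of small and intermediate conductance, Kcnn4 and Kcnn3 could be measured. Kcnn4 stood at 4.25 ± 0.393 CPM in controls, 7.30 ± 0.798 after injury, 9.96 ± 4.02 after injury with stimulation and 8.66 ± 2.41 with stimulation alone (n = 3 each). It rose against control with stimulation alone (log2 fold change 1.02 ± 0.32, adjusted p = 0.024) and with injury plus stimulation (1.22 ± 0.32, adjusted p = 0.016). Neither injury alone (0.78 ± 0.32, adjusted p = 0.076) nor stimulation of injured mice against injured mice (0.44 ± 0.31, adjusted p = 0.64) passed the test. Kcnn3 had 1.47 ± 1.03 CPM in controls and passed in no comparison (injury −0.96, adjusted p = 0.46; stimulation after injury 0.18, adjusted p = 0.97). The call with stimulation alone was lost without control replicate 1 or 3 or without its own replicate 1 or 2 (adjusted p up to 0.15). The call with injury plus stimulation was lost without control replicate 1 or 3 or without its own replicate 1 or 3 (adjusted p up to 0.097). With a GC content and length trend removed, stimulation alone gave 0.79 (adjusted p = 0.13) and injury plus stimulation 1.19 (adjusted p = 0.033).

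Kcnn4 lies on GRCm38 chromosome 7 at 24370263 to 24386690, and its counts came from the interval 24383731 to 24384067, deposited as Gm44971, with 59 bp of coding and 278 bp of untranslated or noncoding exon. Kcnn3 lies on chromosome 3 at 89520164 to 89675132 and was read through 1991 bp of its exons, 1793 of them untranslated or noncoding, under an interval deposited as Chrnb2. Another 315 bp of Kcnn3 exons lay under an interval deposited as 4632404H12Rik (0.596 CPM), which did not take the name. Exons of Kcnn1 lay only under an interval shared by 3 genes, and Kcnn2 had none. The interval deposited as Kcnn3 had 74.96 CPM and lies over Shc1 exons in GRCm38. The interval deposited as Kcnn4 (7.36 CPM) lies over Zfp180, Gm36694 and Gm44943.

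**Figure D1:**
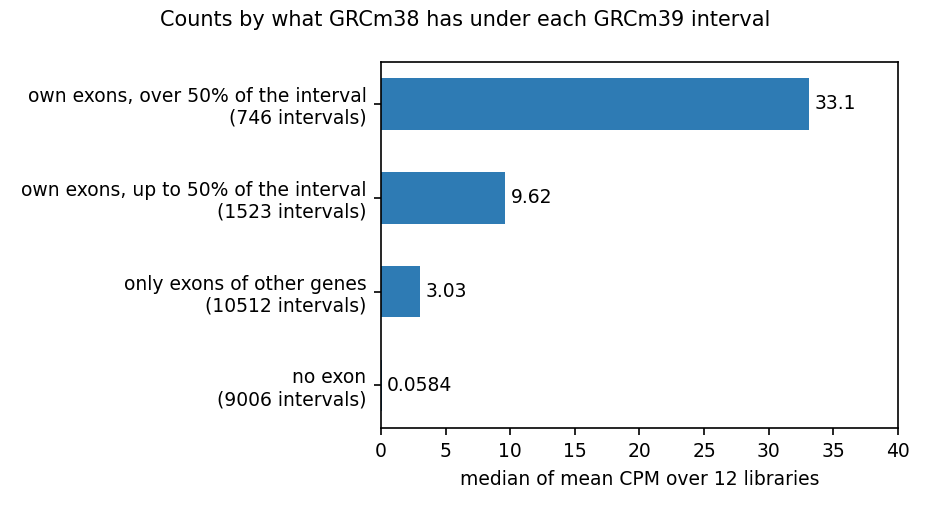
Median over protein-coding counting intervals of the mean CPM (horizontal axis) in 12 libraries, by what the GRCm38 gene models have at the same coordinates. Bars are 9006 intervals with no exon (0.0584 CPM), 10512 with only other genes' exons (3.03), 1523 with up to 50% own exons (9.62) and 746 with more (33.1).

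Genes of myelin and of the coverings of the brain were higher after keratectomy. More nerve root or meningeal tissue in the injured dissections could give the same pattern and stays open. Ptgds, a prostaglandin synthase made by meningeal cells and oligodendrocytes, rose from 5226 ± 258 to 21985 ± 404 CPM (log2 fold change 2.07 ± 0.31, adjusted p = 0.00059, n = 3 each). The myelin genes Mog (2.06 ± 0.33, adjusted p = 0.00099), Mag (2.04 ± 0.27, adjusted p = 0.00025) and Cldn11 (1.89 ± 0.34, adjusted p = 0.0017) rose to a similar degree, and Mog went from 28.7 ± 6.79 to 119.7 ± 37.7 CPM. Slc6a13, a GABA transporter of meningeal cells, rose by 1.72 ± 0.17 (adjusted p = 9.6e-05), and Agt, the angiotensin precursor of astrocytes, by 2.33 ± 0.27 (adjusted p = 0.00014). All 3 oligodendrocyte markers, 5 of 6 myelinating Schwann cell markers and 5 of 8 fibroblast and meningeal markers were higher and none lower, and the same counts passed when adjusted over the list alone. The lists gave camera adjusted p = 0.023, 0.0025 and 0.0080, which became adjusted p = 0.458, 0.426 and 0.458 with an estimated correlation. Mog was read through 114 bp of coding exon (GRCm38 chromosome 17, 37010743 to 37023398). Ptgds was read through 1649 bp, 567 of them coding (chromosome 2, 25466709 to 25470046).

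Injury also raised immediate early genes, transcribed within minutes of cell activation. There 7 of 9 were higher (8 adjusted over the list alone), with a median log2 fold change of 1.22 and adjusted p = 0.0025, or adjusted p = 0.518 with an estimated correlation. The phosphatase gene Dusp1 rose by 1.65 ± 0.23 (adjusted p = 0.00043) and Klf4 by 1.18 ± 0.23 (adjusted p = 0.0023). The AP-1 gene Junb rose by 1.30 ± 0.20 (adjusted p = 0.00072), a call lost once the GC and length trend was removed (0.50, adjusted p = 0.062). Antigen presentation genes were higher for 7 of 9 (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.011, or adjusted p = 0.73 with an estimated correlation), led by the peptide transporter Tap2 (1.37 ± 0.23, adjusted p = 0.0012). With the trend removed that list had adjusted p = 0.65. Endothelial markers were higher for 3 of 6, and the same 3 adjusted over the list alone, including Tie1 (1.11 ± 0.21, adjusted p = 0.0020; list adjusted p = 0.020, or adjusted p = 0.458 with an estimated correlation).

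Nuclear oxidative phosphorylation genes were higher for 6 of 12 after injury, also when adjusted over the list alone, among them Uqcrc1 (1.02 ± 0.22, adjusted p = 0.0031) and Ndufa10 (0.99 ± 0.23, adjusted p = 0.0048). The list had adjusted p = 0.034, or adjusted p = 0.73 with an estimated correlation, and 0.98 with the GC and length trend removed, and its call was lost in 6 of 12 fits with a library left out. Among genes that fell were the cell adhesion gene Negr1 (−2.36 ± 0.49, adjusted p = 0.0029), the axon guidance receptor Robo2 (−1.995 ± 0.42, adjusted p = 0.0029), the kinase Rock2 (−2.53 ± 0.48, adjusted p = 0.0019) and the glial cadherin Cdh19 (−1.12 ± 0.24, adjusted p = 0.0030). Of 5 satellite glial markers, which wrap the neurons, 3 were lower and 1 higher (the same adjusted over the list alone; list adjusted p = 0.504).

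Several groups named for the injury did not move as groups. Only 3 of 30 axon injury response genes were tested. Of these 1 was lower and none higher (1 of each adjusted over the list alone, list adjusted p = 0.951). Ecel1 did not pass (2.11 ± 0.81, adjusted p = 0.057). Ecel1 and Cacna2d1 reached at most 2.66 and 2.89 CPM in any library. So few genes cannot show whether an axon injury response was present. None of 3 peptidergic nociceptor genes passed in either adjustment, with Tac1, the substance P precursor, at −0.03 (adjusted p = 0.91). Of 5 non-peptidergic nociceptor genes, 2 were higher and 1 lower in both adjustments, the ATP receptor P2rx3 falling by −0.56 ± 0.17 (adjusted p = 0.021; lost without control replicate 2, injury replicate 1 or injury replicate 2) while the sodium channel Scn11a rose by 0.69 ± 0.21 (adjusted p = 0.018). Macrophage markers split into 3 higher, 1 lower and 3 not passing, alike when adjusted over the list alone. Ctss rose by 0.92 ± 0.19 (adjusted p = 0.0029) and C1qc by 1.18 ± 0.18 (adjusted p = 0.00063).

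In total 4046 of 13053 intervals differed between injured and control ganglia, 2520 higher and 1526 lower, and by name 930 genes were higher and 603 lower. The excess of higher calls was not stable, at 2782 higher and 2621 lower with only the groups compared, 2488 and 2359 without replicate 2 and 1855 and 1791 without replicate 3 of the injured and stimulated group. Leaving out replicate 1, 2 or 3 of stimulation alone gave 1860 and 1755, 1942 and 1824, or 2139 and 1984. At unadjusted p under 0.05 there were 5531 intervals. Leaving out control replicate 3 or injury replicate 2 reduced the count to 2683 or 2465. Across named genes the log2 fold change rose with GC content (rank correlation 0.45) and fell with transcript length (−0.35). After removal of that trend 682 of 1532 called genes stayed called.

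**Figure D2:**
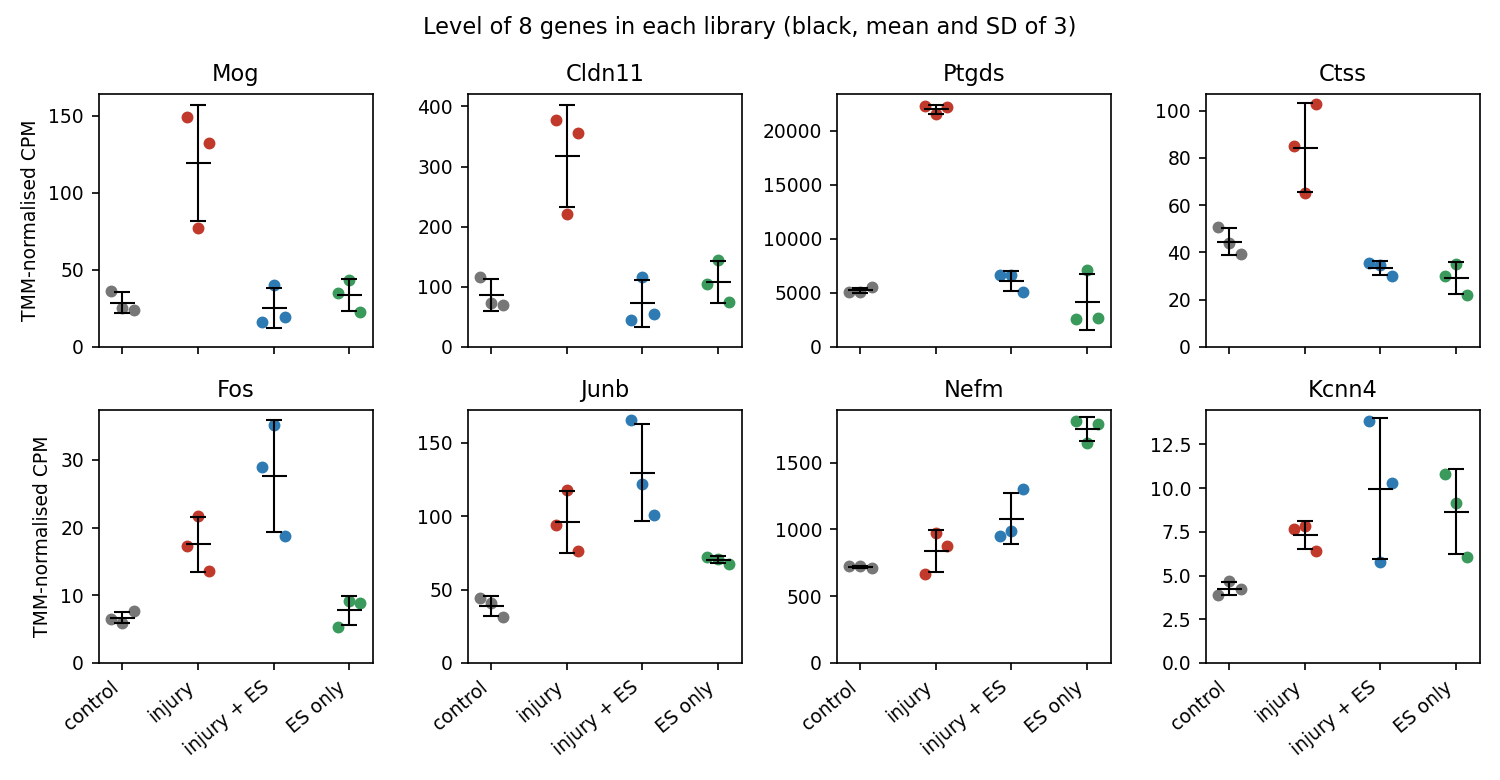
CPM (vertical axes, linear) of Mog, Cldn11, Ptgds, Ctss, Fos, Junb, Nefm and Kcnn4 in each of 12 libraries, by group. Points are libraries, and black marks are the mean and standard deviation of 3, such as 119.7 ± 37.7 for Mog after injury and 25.3 ± 12.8 after injury with stimulation.

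In injured mice given stimulation, Ptgds and Slc6a13 stood near their control levels, and Mog and Cldn11 did so only in replicate 2 (39.98 and 116.5 CPM). In replicates 1 and 3 both lay below every control (Mog 16.4 and 19.5 CPM beside 24.2 to 36.5, Cldn11 45.5 and 54.9 beside 69.1 to 116.6). Against injury alone Mog fell by −2.24 ± 0.33 (adjusted p = 0.0034), to 25.3 ± 12.8 CPM, and Cldn11 by −2.14 ± 0.34 (adjusted p = 0.0061), to 72.3 ± 38.6 CPM beside 86.0 ± 26.5 in controls (n = 3 each). Slc6a13 fell by −1.65 ± 0.17 (adjusted p = 0.00026), Mag by −1.80 ± 0.27 (adjusted p = 0.0030) and Agt by −1.73 ± 0.26 (adjusted p = 0.0033). Ptgds fell by −1.84 ± 0.30 (adjusted p = 0.0060), to 6121 ± 921 CPM, and did not pass without replicate 2 of the stimulated group (−1.84, adjusted p = 0.078). The enzyme gene Fa2h, which hydroxylates myelin lipids, fell by −1.05 ± 0.18 (adjusted p = 0.0072) but stayed above control (0.85 ± 0.18). Of 13053 intervals 201 were called, 196 lower and 5 higher. Lower calls outnumbered higher ones in every fit tried, from 127 against 0 with only the groups compared and 156 against 1 with a replicate block to 299 against 69 with DESeq2, 822 against 221 with voom quality weights and 256 against 82 without replicate 1 of the injured and stimulated group. By name 98 genes were lower and 2 higher, Gm43279 and Adam22, a receptor of myelinated axons (0.72 ± 0.15, adjusted p = 0.024; 0.63 ± 0.20, adjusted p = 0.12 with the GC and length trend removed). The count moved when single libraries were left out, to 5 without replicate 3 and 338 without replicate 1 of the injured and stimulated group. It was 44 without injury replicate 1, 91 without injury replicate 3 and 116 without replicate 1 of stimulation alone. Slc6a13 passed in all 12 fits with a library left out. Mog, Cldn11, Mag and Agt each lost their call in 1 of them, Fa2h and Ptgds in 2 and Adam22 in 3.

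Fibroblast and meningeal markers were lower for 4 of 8 (7 adjusted over the list alone; adjusted p = 1.4e-10, and adjusted p = 0.033 with an estimated correlation). Myelinating Schwann cell markers were lower for 4 of 6 in both adjustments (adjusted p = 8.0e-07, and adjusted p = 0.033 with an estimated correlation). They were Cnp (−1.09 ± 0.19, adjusted p = 0.0072), Mal (−0.92 ± 0.15, adjusted p = 0.0061), Mag and Fa2h. The Cnp and Mal calls were lost in 2 and 1 of 12 fits with a library left out. Prx overlapped between the groups (2750, 4817 and 2672 CPM after injury, 4096, 1767 and 2400 with stimulation). Which cells these calls came from was not tested. Oligodendrocyte markers were lower for 2 of 3 (3 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.048 with an estimated correlation). Only these 3 lists, of 40 tested in 6 comparisons, passed with an estimated correlation. The forkhead gene Foxc1, needed for meningeal development, fell by −1.50 ± 0.29 (adjusted p = 0.013), the matrix gene Fn1 by −1.41 ± 0.29 (adjusted p = 0.017) and Dcn by −0.81 ± 0.16 (adjusted p = 0.016). The Foxc1, Fn1 and Dcn calls were lost in 2, 3 and 5 of 12 fits with a library left out, in each case without injury replicate 1 and without replicate 3 of the injured and stimulated group.

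Macrophage markers were lower with stimulation after injury for 4 of 7 in both adjustments (adjusted p = 0.0030, or adjusted p = 0.0687 with an estimated correlation). The lysosomal protease gene Ctss fell by −1.33 ± 0.19 (adjusted p = 0.0029), from 84.3 ± 18.9 to 33.4 ± 2.95 CPM, and the complement gene C1qc by −0.93 ± 0.18 (adjusted p = 0.011; lost without injury replicate 1 or 3 or replicate 3 of the stimulated group). The other called members, Aif1 (−1.10, adjusted p = 0.020) and Lyz2 (−0.70, adjusted p = 0.026), did not pass with the GC and length trend removed (−0.88 and −0.54, adjusted p = 0.054 and 0.083). Astrocyte markers were lower for 1 of 3, Agt (3 adjusted over the list alone; adjusted p = 0.00053, or adjusted p = 0.191 with an estimated correlation). Endothelial markers were lower for 1 of 6 in both adjustments (adjusted p = 0.0060, or adjusted p = 0.191 with an estimated correlation). Mitochondrially encoded genes were lower for 1 of 3, mt-Nd3 (−1.03 ± 0.23, adjusted p = 0.028), and for 3 adjusted over the list alone (adjusted p = 0.0024, or adjusted p = 0.191 with an estimated correlation). The mt-Nd3 call was lost in 6 of 12 fits with a library left out while its log2 fold change stayed between −1.17 and −0.80.

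Other lists passed after injury with stimulation although no member passed over all genes. Sensory neuron identity genes (median log2 fold change 0.26, none of 5 in either adjustment) had adjusted p = 0.039, or adjusted p = 0.527 with an estimated correlation. Mechanoreceptor genes (median 0.34, none of 6 in either adjustment) had adjusted p = 0.043, or adjusted p = 0.355 with an estimated correlation. Lower as lists were antigen presentation genes (none of 9 in either adjustment), bone genes (1 of 3 adjusted over the list alone) and skeletal muscle genes (1 of 5 adjusted over the list alone), each at adjusted p = 0.039, or adjusted p = 0.562, 0.191 and 0.562 with an estimated correlation. Ribosomal protein genes (1 of 6 lower adjusted over the list alone) had adjusted p = 0.033, or adjusted p = 0.355 with an estimated correlation. Each of these list calls was lost in 3 to 6 fits with a library left out. Without replicate 2 of the stimulated group the ribosomal list had adjusted p = 0.270 and the muscle list 0.076. Immediate early genes did not pass (none of 9 over all genes, 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.125).

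**Figure D3:**
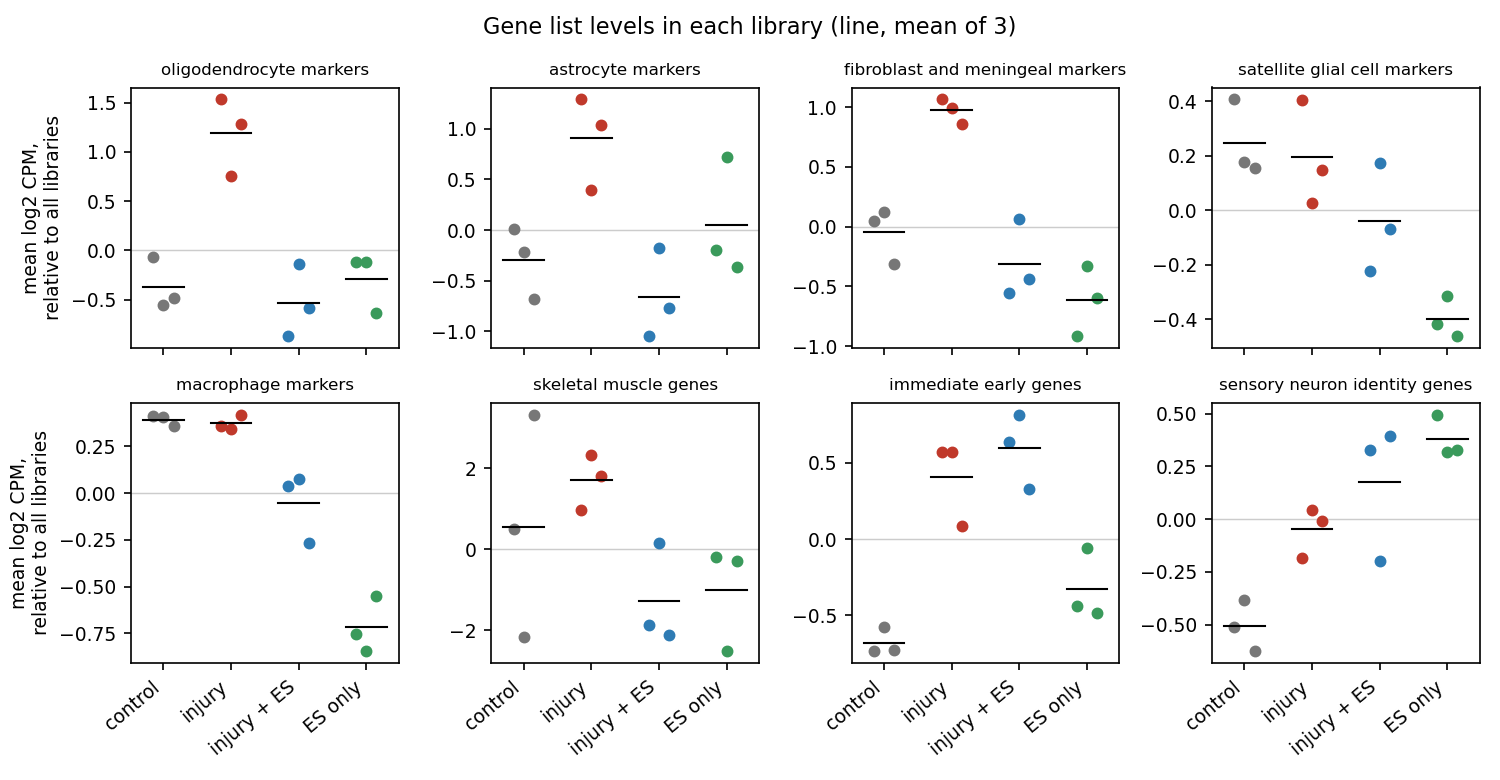
Mean log2 CPM of the members of 8 gene lists relative to all libraries (vertical axes) in 12 libraries by group. Points are libraries and lines are means of 3, and muscle scores ran from −2.15 to 3.33 within the controls.

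Sensory neuron identity genes were higher with stimulation alone than in controls. This comparison followed GC content most closely (rank correlation 0.63), and 23.5% of its called genes stayed called with the GC and length trend removed. Nefm, a neurofilament subunit, rose from 721 ± 7.22 to 1749 ± 88.3 CPM (log2 fold change 1.28 ± 0.17, adjusted p = 0.00012, n = 3 each). The secreted neuropeptide precursor Vgf rose by 1.76 ± 0.26 (adjusted p = 0.00020) and the neurotrophin receptor Ngfr by 1.29 ± 0.17 (adjusted p = 9.8e-05). All 5 sensory neuron identity genes were higher in both adjustments (median 0.86, adjusted p = 0.0072, or adjusted p = 0.434 with an estimated correlation), among them Thy1 (1.05 ± 0.23, adjusted p = 0.0025) and Avil (0.86 ± 0.15, adjusted p = 0.00050). Scn10a, the sodium channel of nociceptors, rose by 0.50 ± 0.17 (adjusted p = 0.030) and lost the call with the GC and length trend removed (0.19, adjusted p = 0.50). It also lost it without control replicate 1 or 3, replicate 1 or 3 of stimulation alone, or replicate 3 of injury with stimulation (adjusted p up to 0.16). Nefm was read through 302 bp of exon (GRCm38 chromosome 14, 68082590 to 68124846).

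Mitochondrially encoded genes fell with stimulation alone, as did single genes of matrix and macrophages. Dcn, a collagen-binding proteoglycan, fell from 2952 ± 524 to 867 ± 63.0 CPM (−1.77 ± 0.17, adjusted p = 2.2e-05) and Postn by −1.93 ± 0.33 (adjusted p = 0.00057), while the protease inhibitor gene Timp2 rose by 0.98 ± 0.19 (adjusted p = 0.0010) and the matrix list did not pass (1 higher and 2 lower of 14 in both adjustments, adjusted p = 0.823). Lyz2 fell by −0.88 ± 0.16 (adjusted p = 0.00067) and the macrophage gene F13a1 by −2.55 ± 0.65 (adjusted p = 0.0068), although the macrophage list, with 4 of 7 lower (5 adjusted over the list alone), had adjusted p = 0.0525. All 3 tested mitochondrially encoded genes were lower in both adjustments (median −1.60, adjusted p = 0.0072, or adjusted p = 0.434 with an estimated correlation). mt-Co2 fell by −1.97 ± 0.30 (adjusted p = 0.00029) and mt-Nd3 by −1.60 ± 0.23 (adjusted p = 0.00019), the mt-Nd3 call being lost with the GC and length trend removed (−0.53, adjusted p = 0.10). Cdh19 fell by −1.60 ± 0.24 (adjusted p = 0.00024), and satellite glial markers were 4 lower and 1 higher of 5 in both adjustments (adjusted p = 0.092). The muscle genes Sln (−5.05 ± 1.29, adjusted p = 0.0079) and Trdn (−4.96 ± 1.13, adjusted p = 0.0033) fell, from control levels that varied widely (5.75 ± 5.75 and 3.47 ± 3.99 CPM).

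Stimulation alone changed 3896 of 13053 intervals against control, 2371 higher and 1525 lower, and by name 881 genes were higher and 658 lower. The count ranged from 2640 to 4593 when single libraries were left out. The log2 fold change followed GC content more closely here than in any other comparison (rank correlation 0.63), and the trend held 35.3% of its variance across genes. With the trend removed 362 of 1539 called genes, 23.5%, stayed called.

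**Figure D4:**
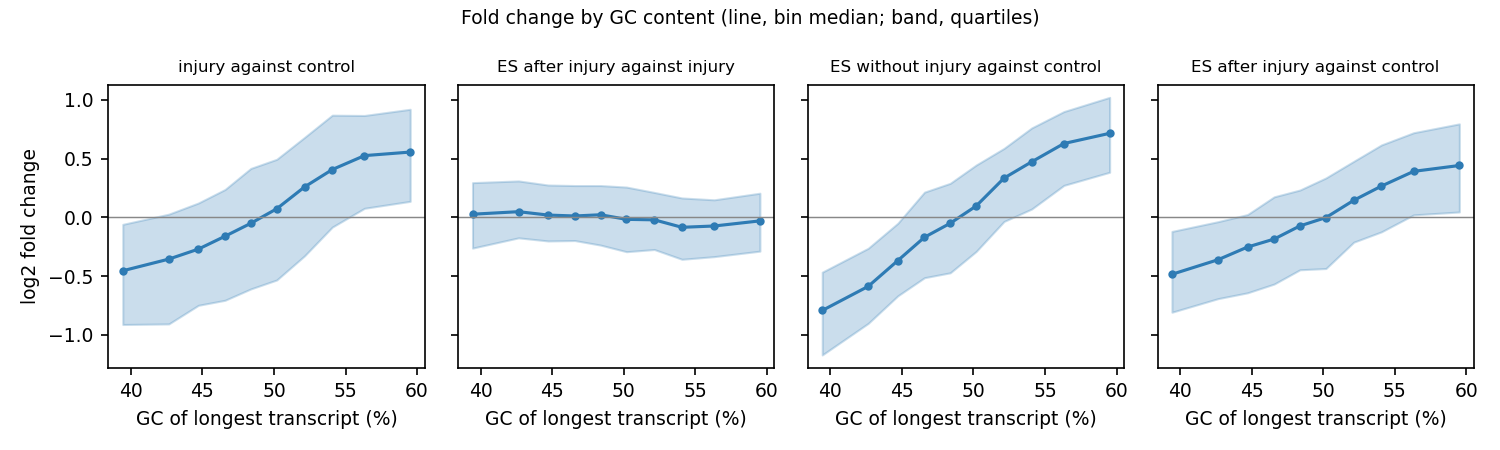
Log2 fold change (vertical axis) by GC content of the longest transcript (horizontal axis, %) in 10 bins of named genes for 4 comparisons. Lines are bin medians and bands are quartiles, with rank correlations of 0.45 for injury and 0.63 for stimulation alone.

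Injury with stimulation left immediate early genes above control. Fos, an AP-1 transcription factor, rose from 6.69 ± 0.859 to 27.6 ± 8.26 CPM (log2 fold change 2.04 ± 0.28, adjusted p = 0.0036, n = 3 each), Ier2 by 1.85 ± 0.23 (adjusted p = 0.0029) and Junb by 1.74 ± 0.20 (adjusted p = 0.0016). In both adjustments 7 of 9 were higher (adjusted p = 7.2e-06, or adjusted p = 0.807 with an estimated correlation). Sensory neuron identity genes were higher for 4 of 5 in both adjustments (adjusted p = 0.0071, or adjusted p = 0.812 with an estimated correlation), with Thy1 at 1.19 ± 0.23 (adjusted p = 0.0049). Oxidative phosphorylation genes encoded in the nucleus were higher for 6 of 12 in both adjustments (adjusted p = 0.018, or adjusted p = 0.85 with an estimated correlation), with Uqcrc1 at 1.03 ± 0.22 (adjusted p = 0.0063). Those encoded in mitochondria were lower for 2 of 3 (3 adjusted over the list alone; adjusted p = 0.041, or adjusted p = 0.812 with an estimated correlation), a list call lost without replicate 2 (adjusted p = 0.115). The zinc finger gene Plag1 fell by −1.91 ± 0.45 (adjusted p = 0.0095), while Mog (−0.18, adjusted p = 0.76; −0.70, adjusted p = 0.13 without replicate 2) and Agt (0.60, adjusted p = 0.13) did not differ from control by the test. Fos was read through 637 bp of exon, 572 of them coding (GRCm38 chromosome 12, 85473890 to 85477273). There were 2247 intervals called, 1604 higher and 643 lower, and by name 551 and 286 genes. That excess was smaller with voom quality weights (2823 higher, 2517 lower) and without replicate 2 of the injured and stimulated group (2366 and 1983). Without replicate 3 of the injured and stimulated group 11 intervals were called, and without its replicate 2 there were 4349. The count was 1034 without control replicate 1, 974 without control replicate 3 and 1007 without replicate 1 of the injured and stimulated group. With the GC and length trend removed 305 of 836 called genes stayed called.

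Averaged over injured and uninjured mice, stimulation lowered Dcn (−1.29 ± 0.12, adjusted p = 2.0e-05), Ctss (−0.98 ± 0.14, adjusted p = 0.00041), Lyz2 (−0.79 ± 0.11, adjusted p = 0.00038) and mt-Co2 (−1.46 ± 0.21, adjusted p = 0.00052), and raised Nefm (0.82 ± 0.12, adjusted p = 0.00052, n = 6 each). In injured mice alone Nefm did not pass (0.37, adjusted p = 0.38), nor did any tested sensory neuron identity gene. There mt-Co2 passed only when adjusted over its list alone. Meningeal markers were lower for 5 of 8 (6 adjusted over the list alone; adjusted p = 1.2e-05, or adjusted p = 0.163 with an estimated correlation) and macrophage markers for 4 of 7 (5 adjusted over the list alone; adjusted p = 0.00045, or adjusted p = 0.119 with an estimated correlation). Mitochondrially encoded genes were lower for 3 of 3 in both adjustments (adjusted p = 0.00029, or adjusted p = 0.23 with an estimated correlation). Sensory neuron identity genes were higher for 4 of 5 (5 adjusted over the list alone; adjusted p = 0.00044, or adjusted p = 0.303 with an estimated correlation). Ribosomal protein genes were lower for 2 of 6 in both adjustments, Rpl26 (−0.70 ± 0.13, adjusted p = 0.0022) and Rps27a (−1.05 ± 0.16, adjusted p = 0.00078), with list adjusted p = 0.021, or adjusted p = 0.36 with an estimated correlation. Oligodendrocyte markers were lower for 2 of 3 and satellite glial markers for 2 of 5 (3 and 4 adjusted over the list alone). Their adjusted p = 0.031 and 0.035 became adjusted p = 0.303 and 0.294 with an estimated correlation. Kcnn4 rose by 0.73 ± 0.22 (adjusted p = 0.037), a call lost in 10 of 12 fits with a library left out, in which its size ranged from 0.58 to 0.88. There were 2017 intervals called, 1153 higher and 864 lower, with 421 and 404 genes by name. The count was 1145 without replicate 3 and 3164 without replicate 2 of the injured and stimulated group. With the GC and length trend removed 278 of 825 called genes stayed called.

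The effect of stimulation differed between injured and uninjured mice for 2507 intervals, being lower in injured mice for 1611 and higher for 896 (591 and 380 genes by name). It was lower in injured mice for Agt (difference in log2 fold change −2.85 ± 0.37, adjusted p = 0.00085), Mag (−2.67 ± 0.37, adjusted p = 0.00087), Pltp (−2.80 ± 0.35, adjusted p = 0.00085) and Mog (−2.46 ± 0.46, adjusted p = 0.0035) (n = 3 per group). All 4 fell with stimulation after injury, with the Pltp call (adjusted p = 0.020) lost in 6 of 12 fits with a library left out, such as −0.87 with adjusted p = 0.055 without replicate 2 of that group. With stimulation alone Pltp rose by 1.63 ± 0.25 (adjusted p = 0.00027), Agt by 1.13 ± 0.26 (adjusted p = 0.0039) and Mag by 0.87 ± 0.26 (adjusted p = 0.018), while Mog did not pass (0.23, adjusted p = 0.64). Agt was highest in replicate 2 of that group (57.6 CPM beside 33.9 and 29.4), with every library above the highest control (23.1). The mean level of astrocyte markers was also highest in that replicate (0.72 beside −0.20 and −0.37 log2 CPM relative to all libraries). The Agt and Mag calls with stimulation alone were lost with the GC and length trend removed (0.70 and 0.33, adjusted p = 0.072 and 0.48), and that of Mag also without control replicate 2 or 3 or replicate 1 or 2 of stimulation alone. It was higher in injured mice for the growth factor gene Hgf (2.70 ± 0.54, adjusted p = 0.0045) and for Cdh19 (1.85 ± 0.34, adjusted p = 0.0029). Lists lower in injured mice were myelinating Schwann cell markers (3 of 6, 5 adjusted over the list alone; adjusted p = 0.0033, or adjusted p = 0.338 with an estimated correlation) and endothelial markers (3 of 6, 4 adjusted over the list alone; adjusted p = 0.0043, or adjusted p = 0.338 with an estimated correlation). Antigen presentation genes were lower for 5 of 9 (6 adjusted over the list alone; adjusted p = 0.013, or adjusted p = 0.682 with an estimated correlation). The excess of lower differences was not stable, at 1079 higher and 1173 lower with DESeq2 size factors, 763 and 683 without replicate 3 of the injured and stimulated group, and 694 and 551 without replicate 1 of stimulation alone. With the GC and length trend removed 129 of 971 called genes stayed called. The count was 1126 without replicate 2 of stimulation alone, 1245 without its replicate 1, 1296 without control replicate 3, 1509 without control replicate 1, 1451 without injury replicate 2 and 1446 without replicate 3 of the injured and stimulated group.

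Across 13053 intervals the change after injury and the change with stimulation of injured mice correlated at −0.57. Unchanged groups sharing the injured libraries gave −0.50 in 20 simulations, ranging from −0.51 to −0.48. The covariance was −0.30 against −0.10 simulated. Without replicate 2 of the injured and stimulated group the correlation was −0.19, weaker than the −0.50 simulated with every library. No simulation was run without that replicate, so −0.19 does not show a reversal beyond the sharing of libraries. Of intervals higher after injury 165 were lower with stimulation, Mog, Cldn11 and Slc6a13 among them. Independent lists would share 37.8, and lists that share the injured libraries are not independent. The effects of stimulation in injured and uninjured mice, which share no library, correlated at −0.03, and 62 of 100 splits within injury state gave a value as high.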

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

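The tests for a lower neuron share and for a control library under another label were chosen only after the result was seen, as were removal of the GC and length trend and removal of mitochondrial and rRNA-like intervals. The neuron share test, a count of satellite glial markers, was set with their values known and replaced their median (−0.39), which had left the share undecided. The effect of stimulation differed between injured and uninjured mice for 2507 intervals, among them myelin and antigen presentation genes such as Mag and Tap2. A count that large at n = 3 per group was checked by regrouping libraries. For each pairwise comparison 1 of 10 splits, the real grouping, reached the real count (4046, 201, 3896 and 2247), and the highest other was 0. With 10 splits a share under 0.05 cannot be reached. For the averaged effect of stimulation 5 of 100 splits reached the real count, up to 3182 intervals, which does not exclude chance, and for the interaction 2 of 100, up to 3041. The splits that reached it kept the real grouping of the uninjured mice, so these counts reflect structure between controls and stimulated uninjured mice. For the correlation of stimulation effects 62 of 100 splits were as high, the highest other being 0.30, so likeness of the 2 effects was not found.

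Every treated group differed from the controls in many genes at once, including Thy1 and Junb. A GC or length dependence of library preparation or sequencing may contribute, since 44.5% of called genes stayed called after injury once the trend was removed. Coverage along transcripts stays open, with a rank correlation of −0.25 between fold change and position from the 3′ end. A fit without mitochondrial and rRNA-like intervals called 4013 intervals, 3775 of them among the 4046, so the count did not rest on those intervals. Its split moved to 2251 higher and 1762 lower. The removal leaves all other counts as they were, so it cannot tell whether library quality that goes with these RNAs plays a part. Whether GC content moved with treatment through handling or through the kinds of genes expressed stays open, because no batch record was used here.

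Oligodendrocyte and meningeal markers such as Mog and Slc6a13 were higher after injury and lower again with stimulation. A lower share of neurons would raise markers of all other cells alike. Of 5 satellite glial markers 3 lay more than 2 standard errors below the lowest called oligodendrocyte or meningeal marker. The same number did with the GC and length trend removed. That count was set with the values known, against markers picked for being higher, so it cannot decide the share. With the trend removed the satellite glial median moved from −0.39 to 0.14, and markers called lower went from 3 to 1. Cdh19 fell (−1.12 ± 0.24, or −0.76 ± 0.20 with the trend removed) where Mog rose (2.06 ± 0.33, or 1.80 ± 0.36), although the satellite glial gene Kcnj10 rose too (1.64). Sensory neuron scores were −0.18 to 0.05 in injured libraries and −0.63 to −0.38 in controls, but the rises of Thy1 and Uchl1 (0.93 ± 0.23 and 0.92 ± 0.24) shrank with the trend removed (0.30 ± 0.18 and 0.21 ± 0.19) and carry no weight here. More nerve root or meningeal tissue in the injured dissections could give the same pattern. The oligodendrocyte and meningeal scores correlated at 0.39 within groups over 12 libraries. In injured replicates 1 to 3 oligodendrocyte scores of 1.53, 0.76 and 1.28 went with astrocyte scores of 1.29, 0.40 and 1.04. Astrocyte and oligodendrocyte scores ranked the libraries alike within every group but the controls. Dissection stays open beside a response in the ganglion.

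Replicate 2 of the injured and stimulated group lay nearer to the controls than to its own group, with less Thy1 and Uqcrc1 than its group mates. Correlations were 0.963 to 0.969 with controls and 0.955 to 0.966 with stimulation alone (highest with replicate 3), against 0.935 and 0.959 with its own group. A control library under this label is unlikely, because its mitochondrial share was 17.2%, beside 17.3% and 16.5% in its group and 22.8% to 28.7% in controls. More rRNA-like reads (2.93% here) could place it there, and over the other 11 libraries that share and the main axis of variation correlated at −0.39 within groups, which settles neither side. Its difference from its group mates rose with transcript length (rank correlation 0.35) and distance from the 3′ end (0.25), and fell with GC content (−0.18). Its place stays open.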

How the results depend on the processing

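Names as deposited, 90% names, removal of mitochondrial and rRNA-like intervals, and the GC and length trend for genes and lists were alternatives chosen after the data were seen. The cause of differences between settings was not tested. Transcript length offsets were not run, because the deposited counts carry no transcript lengths per library. Over the planned and added settings 28 values moved and 57 stayed the same, with single libraries apart.

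Stimulation after injury against injury gave 201 calls, 364 with no filter, 368 with DESeq2, 1043 with voom quality weights and 127 with only the groups compared. Injury plus stimulation against control gave 2247, 5340 with voom and 1125 with only the groups compared. The averaged effect went from 2017 to 4392 and the interaction from 2507 to 4413 with voom. With the GC and length trend removed the named genes called went from 1533 to 890 for injury, 100 to 109 for stimulation after injury, 1539 to 481 for stimulation alone, 837 to 428 for injury plus stimulation, 825 to 366 averaged and 971 to 166 for the interaction. Without replicate 2 of the injured and stimulated group they were 1838, 114, 1796, 1613, 1249 and 852.

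With a replicate block the counts were 3600, 157, 3542, 1802, 1525 and 1915. Replicate numbers did not pair libraries, since 1 of 18 same-number correlations exceeded 0.1 (range −0.26 to 0.20). Lists called were 7, 13, 2, 4, 7 and 3. They were 0, 3, 0, 0, 0 and 0 with an estimated correlation, and 0, 1, 1, 1, 1 and 1 with names as deposited. For stimulation alone 5 lists were called with a replicate block, 5 with 90% names and 4 with the trend removed.

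Leaving out each library gave 2465 to 4847 calls for injury, 5 to 338 for stimulation after injury, 2640 to 4593 for stimulation alone, 11 to 4349 for injury plus stimulation, 1145 to 3164 averaged and 1126 to 3407 for the interaction. Each of these fits repeated the filter on low counts, so the intervals tested and the adjustment could change along with the libraries. The averaged count was 1300 without control replicate 1, 1247 without control replicate 3, 1242 without injury replicate 1 and 1240 without replicate 1 of stimulation alone. Lists ranged over 6 to 8, 9 to 13, 2 to 5, 2 to 6, 4 to 9 and 3 to 7. The correlation of injury with stimulation after injury ranged from −0.65 to −0.19. That of the 2 stimulation effects ranged from −0.13 to 0.15, turning positive without replicate 2 of injury with stimulation (0.15) and without replicate 2 of stimulation alone (0.02). At 1 CPM or more they were −0.58 and −0.02.

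The named genes that turned sign with the GC and length trend removed, none passing then, were after injury Epha7 (0.14) and Ptprz1 (0.14). With stimulation alone they were Tac1 (0.15), Chl1 (0.0734), Epha7 (0.17) and Srebf2 (−0.0706). With injury plus stimulation they were Foxp2 (0.00905) and Ptprz1 (0.0253), and in the interaction Cacnb3 (0.25) and Chl1 (−0.12). Sign changes of values passing in neither fit were not counted as reversed. Named-gene values that stayed the same, weakened or strengthened numbered 886, 1 and 5 at 1 CPM or more, 840, 23 and 45 with DESeq2, and 884, 21 and 3 with DESeq2 size factors. They numbered 665, 207 and 26 with the trend removed, 742, 12 and 154 with voom, and 819, 35 and 54 with no filter. With only the groups compared they were 527, 31 and 22, with a replicate block 849, 54 and 5, and without mitochondrial and rRNA-like intervals 876, 11 and 3.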

Other observations

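The lists and their test were fixed before the data were examined, and the simulated value for the likeness of injury and stimulation alone was chosen only after that result was seen. Many of the same genes differed from control in the same direction after injury and with stimulation alone. Tap2 rose by 1.37 ± 0.23 after injury and 1.38 ± 0.23 with stimulation alone, Uqcrc1 stood at 955 ± 77.6 and 920.0 ± 167 CPM beside 469 ± 10.98 in controls, and Cdh19 fell in both (n = 3 each). There were 1585 intervals higher and 615 lower in both, where independent lists would share 458 and 178. The changes correlated at 0.62, against 0.50 in simulated unchanged groups that share the control libraries, and the covariance was 0.44 against 0.10. Both changes rose with GC content (rank correlations 0.45 and 0.63). The simulated groups held no such trend, so they cannot tell how much of the excess goes with it. The 3 control libraries are common to both and cannot be divided, so part of the excess stays with them.

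Potassium channels other than KCNN rose with stimulation alone for 4 of 9, also adjusted over the list alone, though the list did not pass (adjusted p = 0.124). The fast delayed rectifier Kcnc1 rose by 1.21 ± 0.23 (adjusted p = 0.0011) and the TRESK gene Kcnk18 by 1.17 ± 0.30 (adjusted p = 0.0072). Neither passed once the GC and length trend was removed (0.66 and 0.88, adjusted p = 0.15 and 0.060). Of neurotrophic genes, the receptor Cntfr rose with stimulation alone from 219 ± 12.7 to 559 ± 133 CPM (1.35 ± 0.22, adjusted p = 0.00038). Bdnf fell after injury (−0.75 ± 0.26, adjusted p = 0.037), a call lost with that trend removed (−0.35 ± 0.27, adjusted p = 0.37). Calmodulin and calcium signalling genes were 2 higher and 6 lower of 20 after injury (adjusted p = 0.496), the same adjusted over the list alone.

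Muscle genes varied between libraries of every group. Across both injury states stimulation lowered 3 of 5 (4 adjusted over the list alone; list adjusted p = 0.089), among them Actn3 (−2.02 ± 0.51, adjusted p = 0.016) and Ttn (−2.59 ± 0.84, adjusted p = 0.045), while Ckm did not pass (−3.34, adjusted p = 0.10). Without replicate 2 of the injured and stimulated group Actn3 and Ttn kept their size but did not pass (−2.14 and −2.43, adjusted p = 0.072 and 0.11). Trdn, a muscle gene outside the list, fell by −4.82 ± 0.78 (adjusted p = 0.0010). Muscle scores, the mean log2 CPM of members relative to all libraries, ran from −2.15 in control replicate 2 to 3.33 in control replicate 3. Genes of red blood cells were higher for 2 of 2 after injury with stimulation against control in both adjustments (list adjusted p = 0.144), Alas2 by 1.17 ± 0.34 (adjusted p = 0.025) and Slc4a1 by 1.23 ± 0.40 (adjusted p = 0.043). Without replicate 2 of that group Alas2 kept its size but did not pass (1.12, adjusted p = 0.11), and with the GC and length trend removed neither gene passed (0.92 and 1.07, adjusted p = 0.089 and 0.10). Of 40 lists tested, 16 passed in some comparison and 24 in none. Those 24 covered SK channels, axon injury response, nociceptor and cold-sensing classes, sodium, calcium and other potassium channels, calcium signalling, neurotrophic factors, axon growth, repair Schwann cells, pituitary, red blood cells, neutrophils, interferon response, cytokines, pericytes, matrix, circadian clock, glucocorticoid response, heat shock, cholesterol synthesis and cell cycle. Most members of the axon injury response list were not tested, so not passing does not show that they stayed unchanged.

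The share of counted reads from the mitochondrial genome was 26.6 ± 3.27% in controls, 20.9 ± 1.50% after injury, 17.0 ± 0.422% after injury with stimulation and 12.4 ± 2.08% with stimulation alone (n = 3 each). mt-Co2 moved with it, at 1026 ± 394, 954 ± 216, 492 ± 218 and 263 ± 30.2 CPM. The rRNA-like share was 2.24 ± 0.326%, 1.03 ± 0.233%, 1.50 ± 1.24% and 0.532 ± 0.108%. The 4 Y chromosome genes checked had 0 reads in all 12 libraries.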
